A study of Mus musculus with 12 samples.

How the data were processed

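Messenger RNA was measured in 12 cultures of mouse dendritic cells on 12 single-colour Affymetrix arrays, 1 array per culture. Marrow cells were grown with GM-CSF (20 ng/ml) for 10 days, per the series' design text. Retinoic acid (RA, 10 nmol as labelled), the retinoic acid receptor alpha antagonist of the Ro series named in the labels (Ro, 100 nmol as labelled) or no retinoid was present from the start of culture, each with or without LPS (1 ug/ml). The design text does not give the time of LPS exposure separately. Each of the 6 conditions was measured in 1 BALB/c and 1 BL6 culture, so that replicate 1 of every condition is BALB/c and replicate 2 is BL6.

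The deposited values are probe set intensities on a linear scale, between 0.0195 and 17488. MAS5 is named in the submitters' processing notes, without a version or a target intensity. Tested on the values, the table held no negative value or 0, the array medians ran from 21.4 to 41.8 (a 1.96-fold range) and the trimmed means from 158 to 263, so the arrays had not been brought to 1 common trimmed mean. Detection calls were not used here. The table held 45101 probe sets, of which 34945 were annotated to a single gene, 932 to several, 9211 to none and 64 were controls. Of the single-gene probe sets, 34754 had a gene identifier that matched the reference list of mouse genes, and no symbol needed an update. The single-gene probe sets covered 18193 genes.

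The values were analysed as log2(signal + 16) at the deposited scaling, because the array medians differed by less than 2-fold. The added 16 damps noise near background and understates changes of dim genes. A probe set was kept if it lay above the median of its own array on at least 2 of the 12 arrays, and each gene was represented by the kept probe set of highest mean, which left 12429 genes. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and p-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

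Averaged comparisons (LPS, RA against no retinoid, Ro against no retinoid, RA against Ro, and BALB/c against BL6) came from an additive model of retinoid, LPS and strain on all 12 arrays. Comparisons of single conditions (2 arrays against 2) and the interactions of RA and Ro with LPS came from a model of the 6 conditions plus strain. Interactions of strain with LPS and of strain with RA were added to the additive model 1 at a time. Strain was a block in every model, because the same replicate number stands for the same strain in every condition. The check of this pairing used each condition's difference between the strains: across genes, the differences of any pair of conditions correlated with r from 0.297 to 0.696 over 15 pairs. A batch that follows the replicate number cannot be told apart from strain. The p-values measure the spread between these arrays, and nothing in the labels says that the cultures of 1 strain came from separate animals.

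LPS lowered and Ro raised the median of all tested genes at the deposited scaling, and quantile normalization removes such shifts. Log2 changes in the text are therefore given relative to the median change of the 12429 tested genes in that comparison, with the model's standard error after the plus-minus sign, and folds are computed from these relative changes. No fold is given where the mean signal of a group lay below the highest array median (41.8), called background here, as it did for 62 of 227 named values. The size and order of such changes depend on the added 16. "Rose" and "fell" refer to genes past the adjusted threshold at the deposited scaling. Where quantile normalization changes the share of higher and lower genes by over 10 percentage points, that split is given beside the first one.

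Gene lists of pathways and cell types, 31 in all with 859 entries of which 766 were on the array, were fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes. Lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the data, for lists with at least 5 tested members. With the estimated correlation, 5 of the 16 lists past the threshold for LPS kept it (2 under quantile normalization), and none of those for the other averaged comparisons did (6 for RA, 20 for Ro, 21 for RA against Ro and 6 for strain). The rule for named genes takes, for each averaged comparison, the 8 largest rises and 8 largest falls among genes past the threshold that moved the same way in both strains (for the strain comparison, in all 6 conditions). If fewer than 4 genes pass, it takes the 5 smallest p-values in each direction, as not past the threshold. It adds up to 4 members past the threshold of each list that passes camera or has 3 or more such members, up to 2 members as values from the other lists, and fixed sets of retinoid and LPS response genes. For comparisons of 2 arrays against 2 and for interactions it takes the 5 smallest p-values in each direction among genes past the threshold. The strain labels were checked with H2-Ea. Nnt had been chosen for this as well but could not serve. The text names a part of the genes this rule gives, chosen after their values were seen.

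The models were tested on simulated data made from the real arrays' means and spreads with known changes. For LPS (6 arrays against 6), 71% of genes changed by 1 and 98% of genes changed by 2 on the log2 scale were recovered, with 10 false calls among 179. For RA averaged over LPS (4 against 4) the shares were 50% and 96%, with 10 false calls among 156. For RA without LPS (2 against 2) 79.5% of genes changed by 2 were recovered, with 14 false calls among 173, and for the interaction of RA with LPS 35%, with 4 false calls among 74. RA with LPS, simulated with no change, gave 0 calls.

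Alternatives were plain log2 without an offset, quantile normalization, no filter, no intensity trend, all probe sets, no replicate block, contrasts averaged from the model of 6 conditions, each strain alone, the 4 arrays of a comparison alone, and leaving out each array in turn. The number of arrays limits the precision of every value. A fit of 4 arrays alone has little spread of its own per gene and leans on the spread shared across genes. The doses of RA and Ro differ, so a comparison of the compounds is also a comparison of doses. No genomic positions are given, since the array table carries none.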

Results

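Gene expression was measured in dendritic cells grown from BALB/c and BL6 mouse marrow, on 12 arrays. Each strain gave 1 culture in each of 6 conditions: no retinoid, RA and Ro, each with and without LPS. RA activates retinoic acid receptors and Ro blocks the alpha form of that receptor. LPS, a component of the walls of Gram-negative bacteria, is sensed by a Toll-like receptor and drives dendritic cells to mature. Median signals per array lay between 21.4 and 41.8, and the hybridisation controls between 2488 and 3168. The first principal component (54.2% of the variance) separated arrays with LPS from those without. The second (16.8%) set Ro apart from the other conditions, and the third (10.2%) separated the strains.

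**Figure D1:**
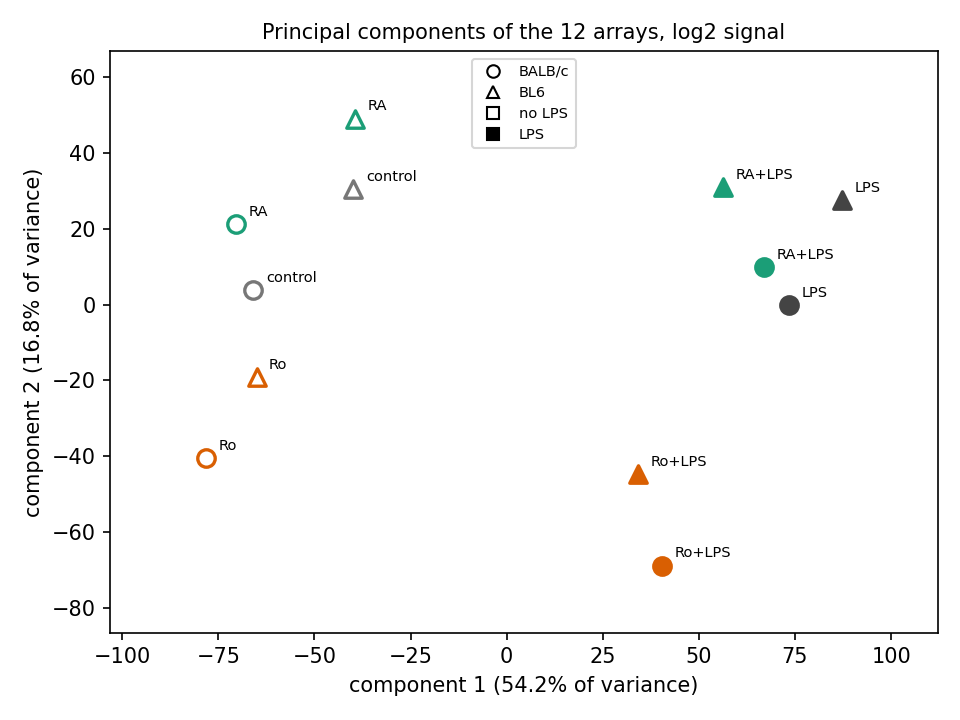
Principal components 1 and 2 of the 12 arrays, from the log2 signals of 12429 genes, with 1 point per array; circles are BALB/c, triangles BL6, open symbols without LPS and filled symbols with LPS, and colours mark no retinoid (grey), RA (green) and Ro (orange). Arrays with LPS lie between 34.3 and 87.3 on component 1 and those without between -78.2 and -39.3, while the 4 Ro arrays lie between -68.8 and -19.1 on component 2.

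The first question was what LPS did across the 3 retinoid conditions, with 6 arrays against 6. Genes of inflammatory cytokines were among the largest rises: Il6 rose by 6.74 ± 0.28 on the log2 scale (107-fold), Il12b by 6.75 ± 0.35 (108-fold), Il1a by 6.20 ± 0.28 and Il1b by 5.47 ± 0.32. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose by 7.84 ± 0.24, from background to a mean signal of 4637, and Inhba, a subunit of activin A, by 5.61 ± 0.35. Smaller rises were seen for Tnf (2.49 ± 0.59, adjusted p = 0.00928) and for Il10, an anti-inflammatory cytokine (1.92 ± 0.31). In BALB/c alone neither passed (adjusted p = 0.144 for Tnf and 0.0531 for Il10). The Tnf signal was 7256 on the BL6 array with RA and LPS and at most 1278 on the other LPS arrays, and in BALB/c cultures with Ro it was lower with LPS (449.5) than without. Among the largest falls were Ccr2, the chemokine receptor of monocytes (-5.84 ± 0.23), and the lectin gene Clec10a (-5.08 ± 0.16). Klk1b27 (-4.48 ± 0.54), Clec4b1 (-4.47 ± 0.22), the immunoglobulin gene Ighm (-4.41 ± 0.28) and Pald1 (-4.35 ± 0.23) also fell.

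Of the fixed list of cytokines of activated dendritic cells, 21 of 25 genes rose with LPS and none fell (camera adjusted p = 1.5e-20, adjusted p = 0.019 with an estimated correlation). Targets and feedback regulators of NF-kappaB rose in 32 of 36 genes, with Nfkbiz at 3.46 ± 0.18 and Socs3, an inhibitor of cytokine signalling, at 3.69 ± 0.27 (adjusted p = 6.8e-26, adjusted p = 0.019 with an estimated correlation). Maturation genes rose in 24 of 30 and fell in 4 (adjusted p = 2.0e-17, adjusted p = 0.047 with an estimated correlation, but 0.147 with it under quantile normalization). In this list Cd40, a costimulatory receptor, rose by 5.22 ± 0.31 and Slamf1 by 4.53 ± 0.35, and Cd200 rose by 4.31 ± 0.15. Ccr7, the receptor that guides dendritic cells to lymph nodes, rose by 2.10 ± 0.30. Interferon stimulated genes rose in 33 of 35 (adjusted p = 1.3e-26, adjusted p = 0.13 with an estimated correlation). Among them were Oasl1 (5.57 ± 0.33), Cmpk2 (5.11 ± 0.36) and Rsad2 (4.94 ± 0.25). Slfn4 rose by 5.72 ± 0.34.

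Stress response genes rose in 16 of 30 and fell in 4, led by the heat shock genes Hspa1a (5.43 ± 0.56) and Hspa1b (5.23 ± 0.66), with adjusted p = 1.2e-09 and adjusted p = 0.047 with an estimated correlation, but 0.147 with it under quantile normalization. Signals of tolerance and T cell differentiation, which include Socs3, rose in 12 of 25 and fell in 3 (adjusted p = 6.5e-08, adjusted p = 0.047 with an estimated correlation, but 0.062 with it under quantile normalization). Of 24 chemokine genes 16 rose and 3 fell (adjusted p = 5.6e-11, adjusted p = 0.082 with an estimated correlation). Cxcl2 had 5.16 ± 0.22, Cxcl3 5.14 ± 0.38 and Cxcl10 4.33 ± 0.51. Nos2, the inducible nitric oxide synthase, rose by 5.19 ± 0.34 and Acod1, which makes itaconate, by 5.29 ± 0.36. Both belong to a list of arginine, tryptophan and oxygen radical genes, of which 9 of 18 rose and 2 fell (adjusted p = 4.9e-09, adjusted p = 0.082 with an estimated correlation). Of 21 genes listed under glycolysis 15 rose and 2 fell, the falls not being past the threshold under quantile normalization (adjusted p = 9.0e-09, adjusted p = 0.23 with an estimated correlation). They included the glucose transporter gene Slc2a1 (2.49 ± 0.32). Among genes of antigen processing for MHC class I, 9 of 17 rose and 2 fell, with the peptide transporter gene Tap1 at 1.91 ± 0.19 (adjusted p = 6.7e-06, adjusted p = 0.23 with an estimated correlation).

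Cell cycle genes fell in 38 of 39, and 35 of these also passed as lower under quantile normalization (adjusted p = 5.6e-11, adjusted p = 0.35 with an estimated correlation). Ube2c, which acts in the exit from mitosis, fell by 4.48 ± 0.37 on the log2 scale, Ccnb2 by 4.39 ± 0.24, the ribonucleotide reductase subunit gene Rrm2 by 4.05 ± 0.28 and Birc5 by 3.98 ± 0.28. Genes of cholesterol synthesis fell in 15 of 20 and rose in 1, with adjusted p = 0.00338 and adjusted p = 0.36 with an estimated correlation. Dhcr7 had -1.86 ± 0.17 and Cyp51 -1.23 ± 0.23. Oxidative phosphorylation genes fell in 31 of 36, 27 of them under both scalings, with a list median of -0.18 (adjusted p = 0.00031, adjusted p = 0.54 with an estimated correlation). Ndufs1, a subunit of respiratory complex I, had -1.08 ± 0.14.

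Cell type markers moved with LPS as well. Granulocyte markers fell in 18 of 23 and rose in 4, with Ngp at -3.94 ± 0.45 and S100a9 at -3.88 ± 0.52 but Orm1 at 4.61 ± 0.43. The list passed only under quantile normalization (adjusted p = 0.12, and 0.00439 under quantile normalization, there with adjusted p = 0.491 with an estimated correlation). Markers of conventional dendritic cells fell in 13 of 20 and rose in 3 (list adjusted p = 0.35, and 0.041 under quantile normalization, there with adjusted p = 0.369 with an estimated correlation), with Cd209a at -4.10 ± 0.40, Itgae at -2.80 ± 0.36 and Naaa at -3.12 ± 0.17. Macrophage and monocyte markers fell in 11 of 23 and rose in 2 (list adjusted p = 0.85): the mannose receptor gene Mrc1 had -4.20 ± 0.33 and Trem2 -2.57 ± 0.24, while the scavenger receptor gene Marco had 4.33 ± 0.53. Rara, which encodes the receptor that Ro blocks, fell by 1.08 ± 0.21 on the log2 scale and Dhrs3, a retinaldehyde reductase, by 1.52 ± 0.19.

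In all, 7291 of 12429 genes passed the threshold with LPS, 1360 higher and 5931 lower (18.7% higher). The median change of all tested genes was -0.41, and under quantile normalization 6602 genes passed, 3030 higher and 3572 lower (45.9% higher). All 1360 higher genes and 3571 of the lower ones passed in the same direction under both. Across genes, which are not independent replicates, the LPS changes of the strains correlated with Pearson's r = 0.876 (Spearman's rho = 0.853). In cultures without retinoid alone (2 arrays against 2) 5655 genes passed, 992 higher and 4663 lower (17.5% higher), around a median change of -0.52. Under quantile normalization 4718 passed, 2016 higher and 2702 lower (42.7% higher). Ptgs2 (8.53 ± 0.32), Hspa1b (7.12 ± 0.33), Cd40 (5.92 ± 0.26), Ccrl2 (5.53 ± 0.23) and Rsad2 (5.19 ± 0.23) were the rises of smallest p. The falls were Ccr2 (-6.02 ± 0.41), Clec10a (-5.24 ± 0.28), Pros1 (-3.47 ± 0.26), Fcgrt (-3.16 ± 0.21) and Mbnl1 (-2.83 ± 0.19). For Ccnb2, Ccr2, Cd209a, Clec10a, Clec4b1, Hspa1a, Hspa1b, Ighm, Il10, Itgae, Marco, Nos2, Orm1, Pald1, Ptgs2, Rara, Rrm2 and Ube2c one group of the averaged LPS comparison lay at background, so that the size of their change depends on the added 16. Without retinoid the same holds for Ccr2, Clec10a, Hspa1b, Pros1 and Ptgs2. Without the BALB/c control array 3014 genes passed, and 3622 without the BL6 LPS array.

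**Figure D2:**
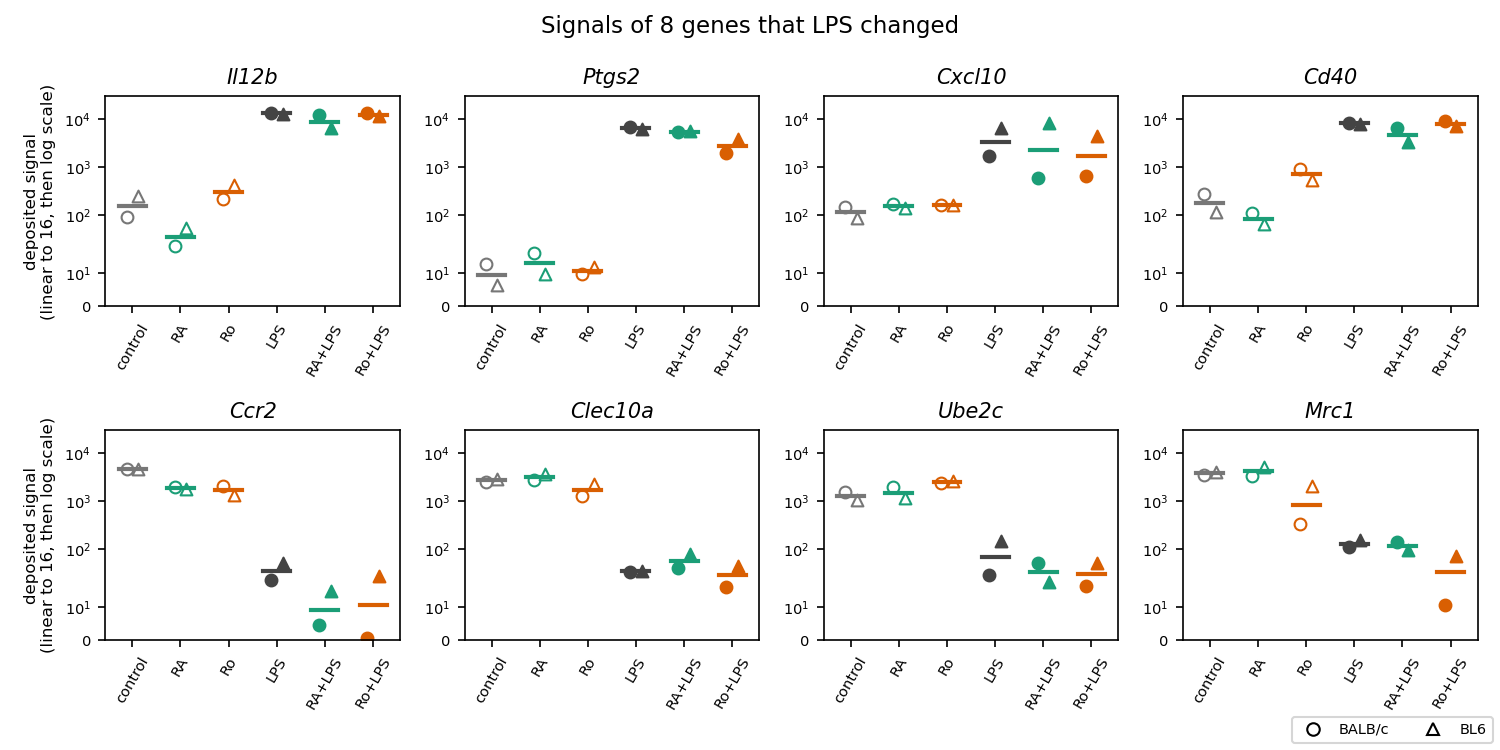
Deposited signal of 8 genes in the 6 conditions, on an axis that is linear up to 16 and logarithmic above; each condition has 1 BALB/c array (circle) and 1 BL6 array (triangle), the horizontal bar is the mean of both taken on the log2(signal + 16) scale, and filled symbols are arrays with LPS. Il12b rose from a mean signal of 125 to 11410 with LPS (n = 6 and 6), whereas Ccr2 went from 2438 to 16.3.

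RA was compared with no retinoid across both LPS states, with 4 arrays against 4. No gene passed the threshold in the additive limma model, while 1026 had an unadjusted p under 0.05. There were 4 genes past it under quantile normalization, all lower, and 41 (9 higher and 32 lower) when the same contrast was averaged from the model of 6 conditions. The values of smallest p are given as not past the threshold. Among them S100a4, a calcium-binding protein gene, had -2.55 ± 0.38 (adjusted p = 0.064, lower in both strains), Kcnn4, a potassium channel gene, -1.70 ± 0.26, S100a6 -1.45 ± 0.21, Ahnak -1.34 ± 0.20 and Btg2 -1.03 ± 0.16. In the other direction Cp, the gene of ceruloplasmin, had 2.47 ± 0.40 (adjusted p = 0.064), the chemokine genes Ccl24 and Ccl8 had 1.96 ± 0.35 and 1.79 ± 0.33, Syngr1 1.46 ± 0.26 and Mfge8 1.42 ± 0.26. Of the genes named here, S100a6, Btg2 and Pfkp (-0.98 ± 0.17) passed under quantile normalization, each with adjusted p = 0.0455; the remaining gene was Arc, named after its value was seen.

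Classical retinoic acid response genes had values above the median gene without passing: Cyp26b1, an enzyme that degrades retinoic acid, had 1.05 ± 0.28 (adjusted p = 0.233), Cyp26a1 0.69 ± 0.41, Dhrs3 0.54 ± 0.23, the receptor gene Rarb 0.40 ± 0.29 and the transglutaminase gene Tgm2 0.23 ± 0.21. Aldh1a2, whose enzyme makes retinoic acid, had -0.30 ± 0.23 and Rara 0.05 ± 0.26. For Rarb both groups lay at background (mean signals 25.5 without retinoid and 39.4 with RA). For Cyp26a1 the group without retinoid did (21.4, against 45.1 with RA). The size of the change of Rarb and Cyp26a1 therefore depends on the added 16. Stra6, a retinol transporter gene, did not pass the filter. Of the lists, maturation genes lay lowest with RA, with a median of -0.59 (adjusted p = 1.6e-10, adjusted p = 0.42 with an estimated correlation). None of its 30 genes passed over all genes, and 15 were lower when adjusted over the list alone; Cd70 and Traf1 both had -1.38, with standard errors of 0.23 and 0.43. Conventional dendritic cell markers had a median of -0.37 (adjusted p = 0.00175, adjusted p = 0.42 with an estimated correlation; Itgae -0.97 ± 0.44). Genes of NF-kappaB had -0.21 (adjusted p = 0.00175, adjusted p = 0.72 with an estimated correlation; Relb -1.09 ± 0.30). Granulocyte markers had a median of 0.76 (adjusted p = 0.00035, adjusted p = 0.72 with an estimated correlation), with Prtn3 at 1.57 ± 0.73 and Ltf at 1.37 ± 0.57. Ccr7 had -1.35 ± 0.36 (adjusted p = 0.271).

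Without LPS, 16 genes differed between RA and control cultures (2 arrays against 2), 4 higher and 12 lower. Arg1, the arginase gene, rose by 3.94 ± 0.49 on the log2 scale (15.4-fold, adjusted p = 0.0134), Cnrip1 by 2.55 ± 0.31, the prostacyclin synthase gene Ptgis by 2.14 ± 0.27 and the chemokine gene Ccl3 by 2.02 ± 0.31. The nuclear receptor gene Nr4a3 fell by 2.70 ± 0.31 on the log2 scale, Cbln1 by 2.62 ± 0.30, Traf1 by 2.35 ± 0.29, the complement gene Cfb by 2.27 ± 0.30 and L1cam by 2.05 ± 0.25. One group lay at background for Cbln1. Under quantile normalization 29 genes passed, 11 higher and 18 lower, with 14 shared, but none passed without strain as a block (0 genes, limma). Each of the 9 genes named here was lost without 1 of up to 7 arrays. Ccl3, Cnrip1 and Ptgis were also lost with plain log2, Ccl3 and Ptgis without the filter, and Ccl3 and Cfb without the intensity trend. Only 1 gene, a higher one, passed when the BALB/c RA array was left out, and without the BALB/c control array 5 were higher and 4 lower, whereas 885 passed when the 4 arrays of this comparison were fitted alone.

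With LPS, no gene passed between RA and no retinoid (1139 at an unadjusted p under 0.05 in limma, and 0 under quantile normalization), although 100 passed when the BALB/c array with RA and LPS was left out and 9 when the 4 arrays were fitted alone. The interaction of RA with LPS gave 0 genes (701 at an unadjusted p under 0.05), so the response to RA was not shown to differ between LPS states. Across genes the RA changes of the strains correlated with r = 0.504 (rho = 0.457) without LPS and r = 0.152 (rho = 0.126) with LPS.

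Ro was compared with no retinoid in the same way (4 arrays against 4). Rnase2a, an eosinophil-type ribonuclease gene, fell by 6.45 ± 0.23 on the log2 scale (adjusted p = 3.0e-08). Retnla and Arg1, genes of alternatively activated macrophages, fell by 5.84 ± 0.68 and by 5.20 ± 0.72, and Apoe, the gene of a lipid carrier, fell by 4.60 ± 0.38 (24.2-fold). The same direction was found for Ear3 (-4.24 ± 0.50), the chemokine gene Cxcl14 (-3.89 ± 0.41), the growth factor gene Igf1 (-3.83 ± 0.23) and Selenbp1 (-3.81 ± 0.71). The largest rises were Rtn1 (3.80 ± 0.32), the costimulator gene Icos (2.95 ± 0.48), the E-cadherin gene Cdh1 (2.82 ± 0.64), Kctd14 (2.77 ± 0.37), the decoy receptor gene Il1r2 (2.54 ± 0.47), Nedd4 (2.43 ± 0.32) and Calcb (2.40 ± 0.36). The Langerhans cell lectin gene Cd207 (2.65 ± 0.83) was high on the Ro arrays without LPS (signals 1649 in BALB/c and 297.8 in BL6) and not with LPS (29.0 and 3.45). It no longer passed without 1 of 5 arrays (adjusted p up to 0.0793), without strain as a block (0.054), in BALB/c alone (0.176) or in BL6 alone (0.223). One group lay at background for Arg1, Cd207, Cxcl14, Icos, Rnase2a and Rtn1, and both groups did for Cyp26a1 and Rarb. The size of the change of all these genes depends on the added 16.

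**Figure D3:**
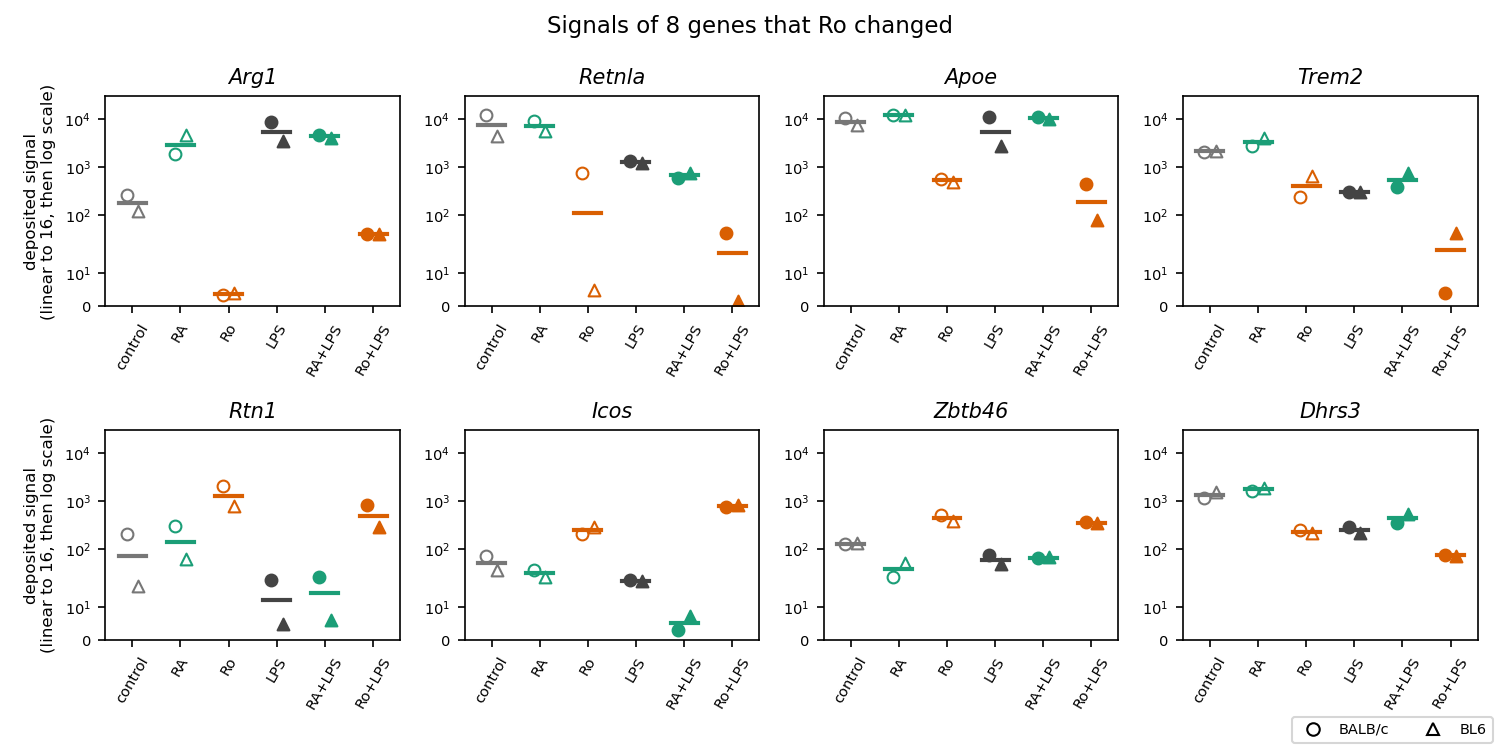
Deposited signal of 8 genes in the 6 conditions, drawn as in the plot of LPS genes: circles are BALB/c, triangles BL6, bars the mean of both arrays on the log2(signal + 16) scale, filled symbols arrays with LPS, and the axis is linear up to 16 and logarithmic above. Apoe had a mean signal of 6999 without retinoid and 323 with Ro (n = 4 and 4), and Rtn1 had 33.2 and 783.

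Macrophage and monocyte markers fell with Ro in 11 of 23 genes and rose in 1 (adjusted p = 3.0e-14, adjusted p = 0.10 with an estimated correlation). The list's median was -1.32, and Trem2 fell by 3.05 ± 0.29 on the log2 scale, Marco by 2.52 ± 0.65 and Mrc1 by 2.08 ± 0.40. Matrix protease and inhibitor genes fell in 10 of 25, with fibronectin (Fn1) at -3.75 ± 0.52 (adjusted p = 3.0e-10, adjusted p = 0.10 with an estimated correlation). The neutrophil collagenase gene Mmp8 had -2.52 ± 0.30, Mmp2 -2.22 ± 0.38 and Timp2 -2.45 ± 0.28. Mmp8 is also 1 of 23 granulocyte markers, of which 3 fell and none rose (adjusted p = 0.00437, adjusted p = 0.546 with an estimated correlation). Pattern recognition receptor genes fell in 9 of 31 (adjusted p = 1.9e-09, adjusted p = 0.17 with an estimated correlation). They included Tlr7 (-1.86 ± 0.25), Clec4d (-1.68 ± 0.25) and Nod1 (-1.64 ± 0.31). Complement and coagulation genes fell in 6 of 19, with F10 at -2.66 ± 0.41 and C3ar1 at -1.86 ± 0.26 (adjusted p = 1.1e-08, adjusted p = 0.17 with an estimated correlation). In the list of lipid uptake, storage and efflux 9 of 30 fell, including the cholesterol exporter gene Abca1 (-1.90 ± 0.27). In the same list 4 rose, including the fatty acid synthase gene Fasn (1.21 ± 0.28), with adjusted p = 1.4e-06 and adjusted p = 0.10 with an estimated correlation. Hmox1 (-2.09 ± 0.22) and Cybb (-1.77 ± 0.21), both of oxygen radical metabolism, fell in a list of 18 with 7 falls and 1 rise (adjusted p = 5.7e-06, adjusted p = 0.20 with an estimated correlation), as did Gpnmb (-1.90 ± 0.30). Interferon stimulated genes fell in 4 of 35, with adjusted p = 1.9e-06 and adjusted p = 0.45 with an estimated correlation. Among them were Iigp1 (-2.07 ± 0.55) and Oas2 (-1.77 ± 0.44).

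Maturation genes rose with Ro in 16 of 30, 12 of them under both scalings, and none fell (adjusted p = 4.9e-06, adjusted p = 0.22 with an estimated correlation). Il2ra rose by 2.13 ± 0.26, Slamf1 by 1.79 ± 0.43 and Cd70 by 1.46 ± 0.23. Of 20 markers of conventional dendritic cells 6 rose, 5 of them under both scalings, and none fell (adjusted p = 0.022, adjusted p = 0.31 with an estimated correlation). Btla rose by 2.19 ± 0.37, the transcription factor genes Zbtb46 by 1.74 ± 0.30 and Irf4 by 1.42 ± 0.32, and Dpp4 by 1.22 ± 0.25. The call of Dpp4 was lost without strain as a block (adjusted p = 0.135), and those of Dpp4, Zbtb46 and Irf4 in BALB/c alone (0.109, 0.0922 and 0.154) and in BL6 alone (0.0696, 0.0655 and 0.0607). Genes of cholesterol synthesis rose in 12 of 20, 7 of them under both scalings, with adjusted p = 0.00148 and adjusted p = 0.32 with an estimated correlation. Fdps had 1.23 ± 0.16, Cyp51 1.13 ± 0.28 and Mvk 1.03 ± 0.22. Among retinoid genes Dhrs3 fell by 2.26 ± 0.23 on the log2 scale (adjusted p = 0.00049) and Aldh1a2 by 1.35 ± 0.23, a call that was lost without strain as a block (adjusted p = 0.0912) and in each strain alone. Cyp26a1 (-0.94 ± 0.41), Tgm2 (-0.52 ± 0.21), Rarb (-0.47 ± 0.29), Rara (0.38 ± 0.26) and Cyp26b1 (0.11 ± 0.28) did not pass.

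Over all genes 2287 passed with Ro, 1746 higher and 541 lower (76.3% higher), with a median change of 0.22. Under quantile normalization 1766 passed, 944 higher and 822 lower (53.5% higher), and 1461 were shared. Fewer genes passed when strain was left out as a block (943), in BALB/c alone (132) and in BL6 alone (188), and the direction turned in BALB/c alone, with 23 higher and 109 lower against 125 and 63 in BL6. Only 858 passed without the BALB/c LPS array. Calls of genes named above were lost in several settings. Without strain as a block these were Marco (adjusted p = 0.169), Iigp1 (0.0628), Nod1 (0.0521), Cyp51 (0.052) and Oas2 (0.052), besides those already given. In each strain alone they were C3ar1, Clec4d, Cyp51, F10, Fasn, Marco, Mvk, Nod1, Oas2, Selenbp1, Slamf1 and Tlr7. In BALB/c alone they were Btla, Calcb, Cdh1, Cybb, Icos, Il1r2, Kctd14, Nedd4 and Timp2, and in BL6 alone Abca1, Arg1, Cd70, Fn1, Gpnmb, Iigp1 and Mrc1 (adjusted p up to 0.252). Marco and Oas2 also no longer passed without 1 of 5 arrays, Iigp1 without 1 of 6 and Nod1 without 1 array.

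Without LPS, Ro changed 327 genes, 180 higher and 147 lower, around a median of 0.16 (55% higher). Under quantile normalization 482 passed, 192 higher and 290 lower (39.8% higher), with 287 shared, so that the direction turned. It turned with plain log2 too (85 and 97), without the BL6 control array (21 and 38), without the BL6 Ro array (34 and 39) and, by less, without any 1 of the 4 arrays with LPS alone or with Ro and LPS. Rnase2a (-6.18 ± 0.27), Fn1 (-5.17 ± 0.43), the acid phosphatase gene Acp5 (-3.94 ± 0.40), Igf1 (-3.70 ± 0.34) and the syndecan gene Sdc1 (-3.33 ± 0.30) were the falls of smallest p. The rises were Rtn1 (3.72 ± 0.42), Bex6 (3.64 ± 0.40), Cd72 (3.10 ± 0.34), Cd7 (2.76 ± 0.30) and the prostaglandin receptor gene Ptger3 (2.73 ± 0.32). The control cultures lay at background for Cd7 and Ptger3 (mean signals 5.66 and 17.8), so that the size of their change depends on the added 16. Ptger3 and Bex6 no longer passed with plain log2, nor did Cd72, Igf1, Rtn1 and Sdc1 without strain as a block. With LPS, 2674 genes changed, 1986 higher and 688 lower, around a median of 0.28 (2511 under quantile normalization, 1388 higher and 1123 lower). Without the BL6 array with Ro and LPS 502 were higher and 576 lower, which turns the direction, and without the BL6 LPS array 847 passed (475 and 372). Arg1 fell by 6.90 ± 0.49 on the log2 scale, Rnase2a by 6.72 ± 0.27, Hspa1b by 4.95 ± 0.33 and the macrophage gene Cd68 by 2.78 ± 0.18. Icos rose by 4.11 ± 0.33, P2ry10 by 2.97 ± 0.31, Enc1 by 2.51 ± 0.26, Kcnk6 by 2.17 ± 0.21 and the glutamate dehydrogenase gene Glud1 by 1.95 ± 0.21. One group lay at background for Arg1, Enc1, Icos and Rnase2a. Without strain as a block 55 genes passed without LPS and 961 with LPS, and with the 4 arrays alone 1105 passed without LPS. Of the genes lower in one state, 94 were lower in both, where independent lists would share 8.14, and 87 were higher in both, against 28.8. In opposite directions 8 genes passed, and the Ro changes of the 2 states correlated with r = 0.458 across genes. Both lists use the same estimate of each gene's spread, so more sharing than in independent lists can arise without a common effect. The strains' Ro changes correlated across genes with r = 0.627 (rho = 0.587) without LPS and r = 0.694 (rho = 0.640) with LPS.

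The interaction of Ro with LPS tested whether the LPS response differed with Ro, and 83 genes passed (limma; 172 under quantile normalization, 79 shared). Each response and each difference is given relative to its own median of all genes, so that a difference departs slightly from the subtraction of the responses. The LPS response of Hspa1b was 7.12 on the log2 scale without retinoid and 2.05 with Ro, a difference of -5.03 ± 0.47 (adjusted p = 0.00174). For the vasodilator peptide gene Adm the LPS response with Ro was 0.26, a difference of -4.70 ± 0.48 from that without retinoid. For G530011O06Rik the responses were 5.57 without retinoid and 1.06 with Ro (difference -4.47 ± 0.38). Hcar2, a receptor of ketone bodies and niacin, had 4.16 and -1.40 (difference -5.52 ± 0.68), and the complement gene C1qa -0.93 and -4.42 (difference -3.44 ± 0.37). In the other direction the lipoprotein gene Apoc2 had -0.99 without retinoid and 4.43 with Ro (difference 5.45 ± 0.47), the growth factor gene Pdgfc -2.67 and 1.55 (4.26 ± 0.43), Rap1gap2 -0.93 and 2.04 (3.01 ± 0.46), Enc1 -2.99 and -0.29 (2.74 ± 0.37) and Sesn1 -2.56 and -0.35 (2.25 ± 0.35). Counted on responses from which the median of all genes was not taken off, the LPS response of the 83 genes was smaller with Ro in 39, larger in 13 and of opposite sign in 31. Adm counts as of opposite sign there, its mean signal with Ro being 52.9 without LPS and 49.1 with LPS. One group lay at background for Adm, Enc1, Hspa1b and Pdgfc. With strain left out as a block 10 genes passed, and Enc1, G530011O06Rik, Hcar2, Rap1gap2 and Sesn1 were not among them. Leaving out 1 array gave between 5 and 166 genes, with the direction turned without the BALB/c LPS array (66 higher and 39 lower, against 32 and 51). C1qa, Enc1, Hcar2, Rap1gap2 and Sesn1 were lost without 1 of up to 5 arrays, and Adm with plain log2.

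RA and Ro were set against each other directly, at their differing doses and with 4 arrays each. The genes that Ro had lowered were the most different: Arg1 was higher with RA by 6.98 ± 0.72, Rnase2a by 6.07 ± 0.23, Cp by 5.58 ± 0.40, and Retnla by 5.35 ± 0.68. Apoe was higher by 5.28 ± 0.38, Cxcl14 by 5.10 ± 0.41, Igf1 by 4.90 ± 0.23 and the eotaxin gene Ccl24 by 4.54 ± 0.35. Lower with RA than with Ro were Icos (-3.65 ± 0.48), the fatty acid transporter gene Slc27a3 (-3.63 ± 0.60), Kctd14 (-3.59 ± 0.37), Rtn1 (-3.33 ± 0.32), and Nedd4 (-3.32 ± 0.32). The adenylyl cyclase gene Adcy6 (-3.27 ± 0.39), the actin-severing gene Scin (-3.27 ± 0.29) and Asgr2 (-3.20 ± 0.80) were also lower. Maturation genes were lower with RA in 22 of 30, 21 of them under both scalings, and none were higher (adjusted p = 7.0e-11, adjusted p = 0.12 with an estimated correlation). Cd70 had -2.84 ± 0.23 and Traf1 -2.41 ± 0.43. Of 20 conventional dendritic cell markers 12 were lower, 8 of them under both scalings (adjusted p = 0.00041, adjusted p = 0.12 with an estimated correlation). Among them were Btla (-2.87 ± 0.37), Zbtb46 (-2.43 ± 0.30) and Irf4 (-1.93 ± 0.32). NF-kappaB genes were lower in 14 of 36 and higher in 3 (adjusted p = 0.028, adjusted p = 0.44 with an estimated correlation; Relb -1.83 ± 0.30), and Ccr7 had -2.02 ± 0.36.

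Macrophage and monocyte markers were higher with RA than with Ro in 14 of 23 and lower in 1, with Trem2 at 3.75 ± 0.29 and Cd68 at 2.39 ± 0.27 (adjusted p = 1.9e-14, adjusted p = 0.098 with an estimated correlation). Matrix protease genes were higher in 12 of 25 and lower in 1 (Mmp8 3.18 ± 0.30; adjusted p = 2.3e-10, adjusted p = 0.075 with an estimated correlation). Pattern recognition receptors were higher in 13 of 31 and lower in 1 (Tlr7 2.53 ± 0.25; adjusted p = 8.1e-10, adjusted p = 0.12 with an estimated correlation). Complement genes were higher in 9 of 19 (C3ar1 2.43 ± 0.26; adjusted p = 5.6e-08, adjusted p = 0.12 with an estimated correlation). Granulocyte and precursor markers, among them Mmp8, were higher in 4 of 23 and lower in none, with a median of 1.02 (adjusted p = 6.5e-07, adjusted p = 0.29 with an estimated correlation). Retinoid response genes separated the compounds in part: Dhrs3 was higher with RA by 2.80 ± 0.23 (6.98-fold), Cyp26a1 by 1.63 ± 0.41 and Aldh1a2 by 1.05 ± 0.23. The calls of Cyp26a1 and Aldh1a2 were lost in each strain alone (adjusted p = 0.204 and 0.167 in BALB/c, 0.138 and 0.184 in BL6), without 1 of 5 and 1 of 3 arrays (up to 0.0727 and 0.0771) and, for Aldh1a2, without strain as a block (0.186). Cyp26b1 (0.95 ± 0.28, adjusted p = 0.0842), Rarb (0.88 ± 0.29), Tgm2 (0.75 ± 0.21, adjusted p = 0.0829) and Rara (-0.33 ± 0.26) did not pass at the deposited scaling, while Cyp26b1 and Tgm2 passed under quantile normalization (adjusted p = 0.0299 and 0.0186).

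Between RA and Ro 2455 genes passed, 666 higher with RA and 1789 lower (27.1% higher), around a median of -0.21; under quantile normalization 2160 passed, 1060 higher and 1100 lower (49.1% higher), with 1762 shared. Without strain as a block 1449 passed, and 549 (295 higher and 254 lower) and 564 (162 and 402) passed in BALB/c and BL6 alone. Leaving out 1 array gave between 1506 and 2573 genes. Besides Cyp26a1 and Aldh1a2, the call of Asgr2 was lost in each strain alone, those of Ccr7, Relb and Traf1 in BALB/c alone and that of Slc27a3 in BL6 alone. One group lay at background for Arg1, Asgr2, Ccl24, Cxcl14, Cyp26a1, Icos, Rnase2a, Scin and Slc27a3, and both groups did for Rarb. The size and order of the changes of all these genes depend on the added 16. Both compounds were set against the same cultures without retinoid, which by chance alone gave a correlation of 0.500 between RA and Ro changes in simulated unchanged groups. The observed correlation across genes was 0.0652. Within single LPS states, for which no simulation was run, it was 0.0737 without LPS and 0.287 with LPS. The observed covariance was 0.0139 and the simulated one 0.0364, a difference of -0.0225. With RA taken from one strain and Ro from the other, so that no array was shared, r was -0.0303 and -0.0473.

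**Figure D4:**
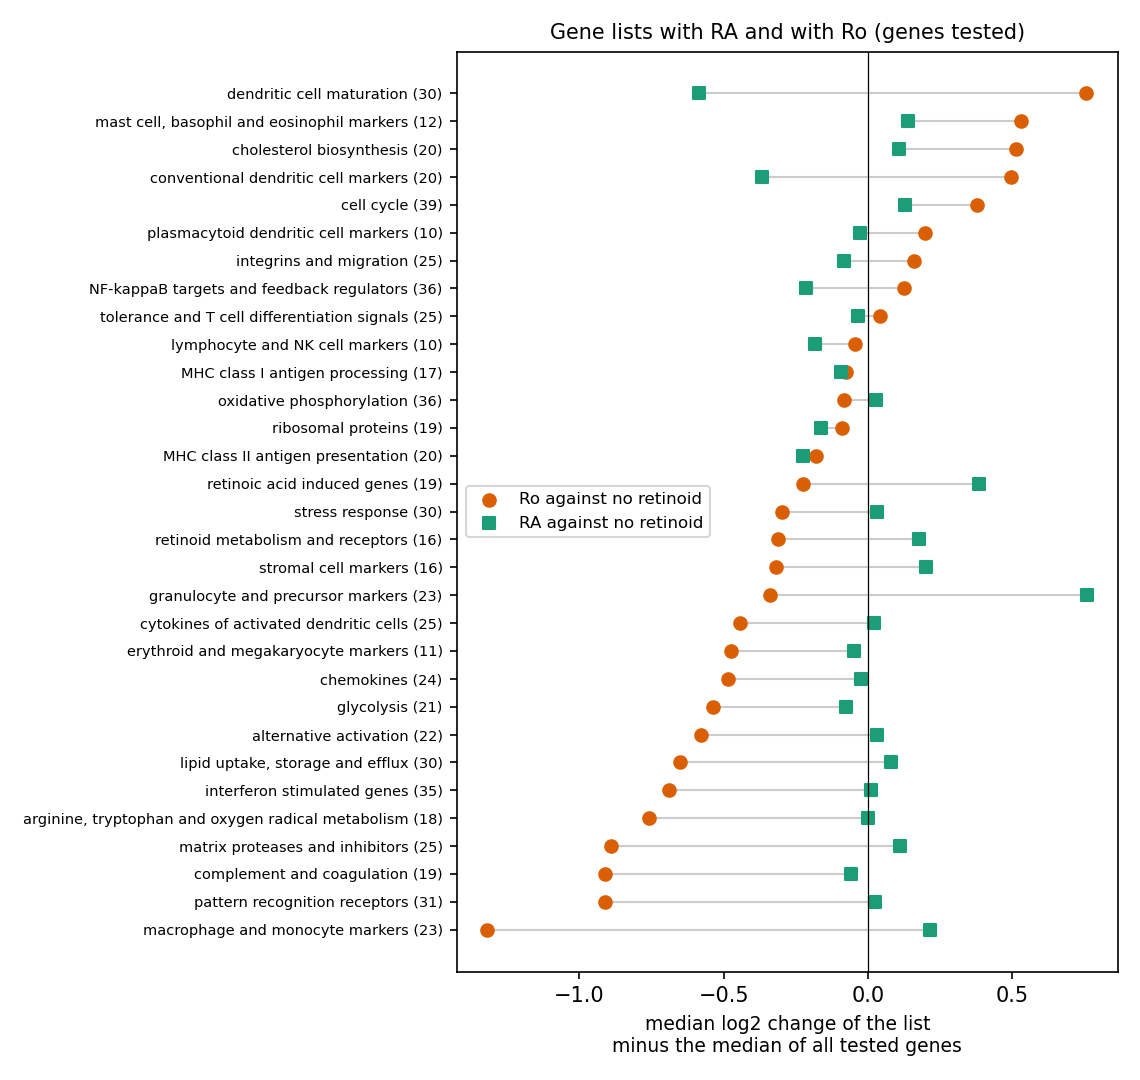
Median log2 change of each of the 31 gene lists, minus the median of all tested genes, for Ro (orange circles) and RA (green squares), each against no retinoid with 4 arrays against 4; the number of genes tested stands after each list's name, and the grey line joins the values of one list. Macrophage and monocyte markers lie at -1.32 with Ro and 0.22 with RA, and maturation genes at 0.75 with Ro and -0.59 with RA.

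The strains were compared across the 6 conditions, with 6 BALB/c arrays against 6 BL6 arrays. H2-Ea, a class II gene that is not expressed in BL6 mice, had a signal of 42.4 in BL6 and 10500 in BALB/c (7.35 ± 0.33), as the labels require. Nnt, whose BL6J allele lacks several exons, did not pass (0.11 ± 0.19, adjusted p = 0.382). Its probe set was not located relative to those exons, so it checks nothing. Higher in BALB/c were the interferon-inducible genes Ifi202b (7.11 ± 0.20) and Ifi44l (5.16 ± 0.33). So were Pdxdc1 (4.72 ± 0.25), the urokinase gene Plau (3.97 ± 0.51), Atp6v0e2 (3.83 ± 0.16) and Tmem87a (3.34 ± 0.28). Lower in BALB/c were Trim12a (-4.85 ± 0.20), Rpgrip1 (-4.25 ± 0.20), Trim34a (-3.89 ± 0.32), Gstm2 (-3.51 ± 0.27), the angiogenin gene Ang (-3.45 ± 0.50), Sirpb1a (-3.22 ± 0.32) and Cav1 (-3.21 ± 0.46). For Pdxdc1 2 of the 3 other probe sets of the gene passed in the opposite direction, and for Trim34a the 1 other probe set did. One group lay at background for Ang, Atp6v0e2, Cav1, Gstm2, Ifi202b, Ifi44l, Pdxdc1, Plau, Rara, Tmem87a, Trim12a and Trim34a, so that the size of their change depends on the added 16.

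Macrophage markers differed between strains in 4 of 23 genes, 3 of them lower in BALB/c, including Marco (-2.52 ± 0.53) and the phagocytic receptor gene Mertk (-1.79 ± 0.21). The list had adjusted p = 0.00032 and adjusted p = 0.96 with an estimated correlation. Cholesterol synthesis genes were higher in BALB/c in 11 of 20, only 2 of them under both scalings (Sqle 0.88 ± 0.22, Nsdhl 0.53 ± 0.13; adjusted p = 0.00255, adjusted p = 0.96 with an estimated correlation). Oxidative phosphorylation genes were higher in 3 of 36 and lower in 5 (Atp5a1 0.56 ± 0.10, Ndufb3 -0.64 ± 0.12; adjusted p = 0.00073, adjusted p = 0.96 with an estimated correlation). Rara (1.35 ± 0.21), Aldh1a2 (0.77 ± 0.19), Cxcl14 (1.89 ± 0.34) and the complement receptor gene C5ar1 (2.20 ± 0.32) were higher in BALB/c, and the lipid carrier gene Fabp4 was lower (-3.01 ± 0.37). In all 1889 genes passed, 1416 higher in BALB/c and 473 lower (75% higher), around a median of 0.14. Under quantile normalization 1894 passed, 891 higher and 1003 lower (47.0% higher), with 1351 shared. Leaving out 1 array gave between 1174 and 1899 genes. The poly-A control signal of dap was 1.83-fold higher in the BALB/c arrays, and a batch that follows the replicate number cannot be told apart from strain.

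Whether the strains answered LPS differently was tested by their interaction, which 15 genes passed. The response in BALB/c minus that in BL6 was negative for 14 of them and positive for 1. The interferon-inducible genes Ifi213 and Mndal had LPS responses of 4.55 and 2.12 on the log2 scale in BL6 and of 1.34 and 0.11 in BALB/c (differences -3.19 ± 0.43 and -1.99 ± 0.30). The value of Mndal in BALB/c is relative to a median gene that fell: its signals went from 4108 to 4523 without retinoid, from 4275 to 3579 with RA and from 5726 to 2577 with Ro. In BALB/c Ifi213 lay at background with and without LPS (mean signals 25.8 and 7.84). Oasl1 had 6.54 and 4.62 (difference -1.89 ± 0.27). Its mean signals with LPS were alike (5923 in BL6 and 5979 in BALB/c), and the strains differed without LPS (63.4 and 336). The integrin gene Itgb7 had -2.83 in BL6 and -5.45 in BALB/c (difference -2.59 ± 0.31), where it lay at background with LPS. The securin gene Pttg1 had 1.30 and -1.14 (difference -2.41 ± 0.29), and the neutrophil chemokine gene Cxcl1 1.96 and 5.26 (difference 3.33 ± 0.41). Under quantile normalization 3 genes passed, 1 positive and 2 negative, all shared, and Ifi213, Mndal and Oasl1 were not among them (adjusted p = 0.0558, 0.0836 and 0.0558). Leaving out 1 array gave between 0 and 33 genes, and each of the 6 genes named here was lost without 1 of at least 5 arrays. Cxcl1, Ifi213 and Mndal were also lost with plain log2, and Mndal without the intensity trend. For the interaction of strain with RA no gene passed (limma; 182 at an unadjusted p under 0.05).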

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

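The tests of a single scaling factor, of the deposited scaling, of shares of macrophages and conventional dendritic cells and of a batch following the strain were chosen after the results they measure were seen. The reading of the test on dim genes was also changed after the results were seen, and 4 readings were tried. The bound set beforehand and a floor of 2 offsets (32) both spoke against dim genes, a floor at the arrays' medians left them open, and the brightest genes by pairs of arrays, used below, spoke against them again. The comparison with splits that part every pair of arrays was added after the results too.

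Of 16 groups of 6 arrays (measures of array quality, each within 1 strain), 2 had an array far from the other 5, where chance gives about 1 such group in 20. The poly-A labelling controls had a mean signal of 210 on the BL6 LPS array, above the other BL6 arrays by 0.733 of the group's range. The ratio of 3' to 5' actin probe sets was 1.16 on the BALB/c control array, set apart by 0.671 of the range. The response to LPS differed with Ro in 83 genes and between the strains in 15 genes, by the tests of the interactions themselves. In data outside the comparisons, the dap labelling control was 1.83-fold higher on the BALB/c arrays, and the 18S ribosomal RNA probe set was 2.74-fold higher on the BL6 arrays, in both cases without overlap between the strains (exact permutation p = 0.00216, the smallest that 6 arrays against 6 can give).

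Most genes past the threshold with LPS were lower at the deposited scaling. As the whole cause, a single scaling factor per array is argued against by the hybridisation controls, which changed by -0.063 (standard error 0.0425) while the median gene changed by -0.41. These controls enter every array in equal amount, so a difference in the amount of labelled sample was not tested. Dim genes sinking into background are argued against as the whole cause too: in 3 groups of genes of equal size by mean signal, the median change was -0.25 at a median signal of 33.0, -0.65 at 204 and -0.36 at 910, so that the dimmest minus the brightest group gave 0.109 and met the bound set beforehand. The dimmest group lies among the arrays' own medians (21.4 to 41.8) and has little room to fall, so this rests on the brightest group, whose median was negative in 6 of 6 pairs of arrays (mean -0.36, standard error 0.0566). Fewer transcripts of many genes after LPS stay open, since among the 1243 brightest genes 57.6% of the calls under quantile normalization were lower, between the bounds set for this explanation.

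With Ro, 11 of 23 macrophage and monocyte markers fell and 1 rose, and 16 of 30 maturation genes rose. Neither list passed camera with an estimated correlation (adjusted p = 0.10 and 0.22). Over both lists, the deposited scaling is argued against as the whole cause, since 24 of the 28 calls (85.7%) kept direction and threshold under quantile normalization. All 11 macrophage falls were kept, but only 12 of the 16 maturation rises, so for the remaining rises the deposited scaling stays open. A smaller share of macrophages stays open: 22 of 23 macrophage and monocyte markers (95.7%) lay below the median gene with Ro, Vcam1 being the exception (values from -4.60 to 0.97), but this list is the pattern itself, so its members could have spoken against a smaller share and cannot show one. A larger share of conventional dendritic cells stays open too, with 16 of 20 markers (80%) above the median gene, at the bound and not beyond it. The rise of this list with Ro was known when the test was chosen, so its members could have spoken against a larger share and cannot show one. These shares were not measured, and a change of expression within the cells stays open.

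The strains differed in many genes. A batch that follows the strain stays open, because the design gives each such batch 1 strain, so batch and strain cannot be told apart. The dap controls differed by 1.83-fold without overlap. All poly-A controls together differed by 1.35-fold and overlapped between the strains (152 to 248 in BALB/c, 128 to 210 in BL6). Sequence differences under the probes may account for part of the calls. Of the genes past the threshold by over 1 on the log2 scale and measured by other probe sets, 149 of 181 (82.3%) had all other sets going the same way, against 400 of 418 (95.7%) for Ro, a gap of 13.4 percentage points. Genetic differences between the mice were not tested apart from these.

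Other splits of the same arrays show how far chance can be excluded. For LPS 1 of 100 splits, the real one, gave as many genes (7291), and the highest other, which kept 5 of the 6 LPS arrays together, gave 5192. Replicate numbers pair the arrays, and of the 32 splits that part every pair, as the real one does, only the real one gave as many (highest other 0). That share (0.0313) is the smallest these splits can give and lies under 0.05, so chance is argued against. For strain, chance between arrays is argued against to the same degree (1 of 99 splits that could be fitted, 1889 genes against 154, and 1 of 32 that part every pair, against 0). These splits treat the cultures of 1 strain as separate, which the labels do not show, so a chance difference between animals is not addressed. For Ro 1 of 35 splits gave as many genes (2287 against 0) and for RA against Ro 1 of 35 (2455 against 1). The bound set beforehand counted all 35, but 27 of them leave both arrays of at least 1 pair on the same side, and the 8 that part every pair (highest other 0 in both comparisons) are too few for a share under 0.05. For RA the real count is 0, which each of the 35 splits reaches whatever the data, so the splits say nothing about it. The highest other (122) divided the arrays without Ro by LPS. With LPS and Ro already in the model, this split measures how the LPS response of the Ro cultures differed from that of the others. For the interaction of strain with LPS (15 genes) the count was as large in 2 of 32 swaps of strain labels, the real one included. The other, with 2126 genes, exchanges the labels in all 3 LPS conditions and so measures the strain difference, which leaves no share under 0.05 within reach.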

How the results depend on the processing

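No named gene past the threshold reversed direction under any alternative run, but part of these runs could hardly show a reversal. With all probe sets the same probe set of each gene was read, and other probe sets of the gene were not. The largest rises and falls had been picked to move the same way in both strains, which bears on the runs of single strains. Over 243 gene values and 4869 alternatives, 4609 kept direction and side of the threshold, 228 (of 70 values) kept direction but no longer passed, 26 newly passed, and 6, none past the threshold, changed sign (Rara for RA, Cyp26b1 for Ro). Values no longer passing numbered 10 with plain log2, 3 each with quantile normalization, no filter and no trend, 0 with all probe sets, 27 without the block, 27 when leaving out 1 array, 34 in BALB/c alone, 28 in BL6 alone and 0 with the 4 arrays of a comparison. Among them were Marco (plain log2, adjusted p = 0.094) and Iigp1 (no filter, adjusted p = 0.053) for Ro. Some settings covered fewer of the 243 values: 211 without the block, 163 in each strain alone and 38 with the 4 arrays of a comparison.

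With all probe sets the counts were 15546 for LPS, 3547 for Ro, 4122 for RA against Ro, 4222 for strain, 11927 for LPS without retinoid, 515 for Ro without LPS, 5037 for Ro with LPS, 137 for Ro by LPS and 38 for strain by LPS, where more features are tested. With plain log2 they were 8 for RA without LPS, 182 for Ro without LPS, 31 for Ro by LPS and 3 for strain by LPS. Quantile normalization gave 4 for RA, 29 for RA without LPS, 172 for Ro by LPS and 3 for strain by LPS. Without the filter there were 8, 41 and 7 for RA without LPS, Ro by LPS and strain by LPS, and without the intensity trend 7 and 31 for the first 2. Contrasts averaged from the model of 6 conditions gave 41 for RA. The cause was not tested for these.

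Without the replicate block, 943 genes passed for Ro, 1449 for RA against Ro, 0 for RA without LPS (limma, 16 with the block), 55 for Ro without LPS, 961 for Ro with LPS and 10 for Ro by LPS, and no other count moved over 1.5 times. Fewer arrays enter in single strains: BL6 alone gave 3556 for LPS, BALB/c and BL6 alone 132 and 188 for Ro and 549 and 564 for RA against Ro. The 4 arrays of a comparison alone gave 885 for RA without LPS, 1105 for Ro without LPS and 9 for RA with LPS. These counts lean on the spread shared across genes, since 4 arrays with strain as a block leave little spread per gene.

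Leaving out 1 array, where a lone array is assumed to vary like the others, gave 6600 to 7340 for LPS, 0 to 2 for RA, 858 to 2557 for Ro, 1506 to 2573 for RA against Ro, 1174 to 1899 for strain, 3014 to 5937 for LPS without retinoid, 1 to 25 for RA without LPS, 59 to 426 for Ro without LPS, 0 to 100 for RA with LPS, 847 to 3223 for Ro with LPS, 0 to 1 for RA by LPS, 5 to 166 for Ro by LPS, 0 to 33 for strain by LPS and 0 for strain by RA. Counts moved over 1.5 times without these arrays (1 is BALB/c, 2 BL6; the cause was not tested). RA: control 1, LPS 1, RA and LPS 1, RA 2 and RA and LPS 2 (1 each), Ro 2 (2). Ro: LPS 1 (858), Ro and LPS 1 (1462), control 2 (1375), LPS 2 (1178), Ro and LPS 2 (936). RA against Ro: RA and LPS 1 (1620), RA 2 (1513), Ro and LPS 2 (1506). Strain: control 1 (1174), control 2 (1234), RA 2 (1216). LPS without retinoid: control 1 (3014), LPS 2 (3622). RA without LPS: control 1 (9), RA 1 (1), Ro 1 (8), control 2 (4), RA 2 (25), Ro 2 (8). Ro without LPS: control 1 (122), Ro 1 (84), control 2 (59), Ro 2 (73). RA with LPS: RA and LPS 1 (100), and Ro 1, LPS 1 and Ro 2 (1 each). Ro with LPS: LPS 1 (1622), Ro and LPS 1 (1524), LPS 2 (847), Ro and LPS 2 (1078). RA by LPS: RA 2 (1). Ro by LPS: control 1 (49), RA 1 (44), Ro 1 (9), RA and LPS 1 (166), Ro and LPS 1 (5), control 2 (8), RA 2 (35), Ro 2 (11), LPS 2 (8), RA and LPS 2 (159). Strain by LPS: RA 1, RA and LPS 1, RA 2, LPS 2 and RA and LPS 2 (0 each), control 1 (4), Ro 1 (6), Ro and LPS 1 (3), control 2 (1), Ro 2 (33).

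Named genes that stopped passing without 1 array follow, each with the number of such arrays and, in brackets, the array with the highest adjusted p and that p (the cause was not tested). Ro: Cd207 5 (control 2, 0.0793), Marco 5 (Ro and LPS 2, 0.105), Nod1 1 (LPS 1, 0.0507), Iigp1 6 (LPS 1, 0.116), Oas2 5 (LPS 1, 0.0972). RA against Ro: Cyp26a1 5 (RA 1, 0.0727), Aldh1a2 3 (RA and LPS 1, 0.0771). RA without LPS: Arg1 1 (control 2, 0.116), Cbln1 3 (RA 1, 0.108), Ccl3 7 (RA 1, 0.386), Cfb 3 (RA 1, 0.164), Cnrip1 3 (control 2, 0.136), L1cam 3 (RA 1, 0.152), Nr4a3 2 (RA 1, 0.108), Ptgis 4 (RA 1, 0.164), Traf1 3 (RA 1, 0.108). Ro by LPS: C1qa 1 (Ro and LPS 1, 0.0704), Enc1 5 (control 2, 0.0844), Hcar2 3 (LPS 2, 0.0794), Rap1gap2 4 (control 2, 0.0941), Sesn1 5 (Ro 1, 0.104). Strain by LPS: Cxcl1 8 (RA 2, 0.135), Ifi213 9 (RA and LPS 2, 0.093), Itgb7 5 (RA and LPS 2, 0.0866), Mndal 7 (RA 2, 0.135), Oasl1 8 (RA 2, 0.106), Pttg1 6 (RA and LPS 2, 0.0866).

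Correlations between strains under quantile normalization and without the filter were 0.872 and 0.859 for LPS, 0.519 and 0.395 for RA without LPS, 0.646 and 0.535 for Ro without LPS, 0.130 and 0.113 for RA with LPS, and 0.667 and 0.629 for Ro with LPS. With an estimated correlation 5 lists passed for LPS (2 with quantile normalization as well) and 0 for RA, Ro, RA against Ro and strain (camera). Signal over background limits dim genes, whose changes the offset damps.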

Other observations

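The test on opposite effects of RA and Ro was chosen after the results were seen.

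Lists not described so far that passed camera follow, none of which passed with an estimated correlation. Each has the genes that rose and fell, the genes tested and the 2 adjusted p values. Camera sets a list against all other genes, so its direction can differ from these counts. It was lower for cytokines with Ro and for both lists with RA. It was higher for pattern recognition receptors with LPS, and for stromal cell markers and stress response between RA and Ro. With LPS the lists were stromal cell markers 5 and 3 of 16 (0.00247, 0.351), ribosomal proteins 0 and 18 of 19 (0.0102, 0.711) and pattern recognition receptors 10 and 12 of 31 (0.022, 0.583). With RA they were ribosomal proteins 0 and 0 of 19 (8.4e-05, 0.723) and MHC class II antigen presentation 0 and 0 of 20 (0.0433, 0.723). With Ro they were glycolysis 0 and 2 of 21 (7.4e-06, 0.317), alternative activation 1 and 5 of 22 (0.000375, 0.182), cell cycle 6 and 0 of 39 (0.0111, 0.68), chemokines 1 and 4 of 24 (0.00152, 0.344) and cytokines 3 and 1 of 25 (0.0211, 0.371). Others were stress response 4 and 5 of 30 (0.00696, 0.317), retinoid metabolism and receptors 0 and 2 of 16 (0.01, 0.222) and genes induced by RA 1 and 4 of 19 (0.0182, 0.371). Between RA and Ro (higher and lower with RA) they were lipid handling 10 and 2 of 30 (5.6e-08, 0.075), interferon stimulated genes 5 and 0 of 35 (5.2e-06, 0.444), chemokines 7 and 4 of 24 (0.000406, 0.291), cholesterol biosynthesis 2 and 13 of 20 (0.0184, 0.444) and glycolysis 3 and 2 of 21 (0.00142, 0.444). Others were alternative activation 7 and 4 of 22 (0.00115, 0.172), metabolism of arginine, tryptophan and oxygen radicals 6 and 1 of 18 (3.0e-05, 0.182), stress response 2 and 2 of 30 (0.00142, 0.227), erythroid and megakaryocyte markers 3 and 1 of 11 (0.0486, 0.444) and stromal cell markers 0 and 1 of 16 (0.0292, 0.444). Others were ribosomal proteins 0 and 3 of 19 (0.00234, 0.561), retinoid metabolism and receptors 4 and 1 of 16 (0.00115, 0.115) and genes induced by RA 5 and 1 of 19 (0.00171, 0.286). Between BALB/c and BL6 (higher and lower in BALB/c) they were cell cycle 8 and 0 of 39 (0.0419, 0.964), complement and coagulation 1 and 2 of 19 (0.0414, 0.964) and ribosomal proteins 0 and 1 of 19 (0.00146, 0.964).

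Of the lists that follow, those of LPS and of RA against Ro did not pass camera at the deposited scaling. Of 12 markers of mast cells, basophils and eosinophils 8 fell with LPS and 1 rose, 4 of the falls and the rise under both scalings (camera adjusted p = 0.559). Of 10 markers of plasmacytoid dendritic cells 6 fell with LPS and 2 rose, 5 and 2 under both scalings (adjusted p = 0.978). With Ro, 2 of 11 erythroid and megakaryocyte markers fell and none rose (adjusted p = 0.0117, adjusted p = 0.336 with an estimated correlation). Genes of MHC class II presentation, central to dendritic cells, were lower with RA than with Ro in 8 of 20 and higher in 3, under both scalings (adjusted p = 0.954).

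A hypothesis from the comparison of RA with Ro is that agonist and antagonist act on the same genes in opposite directions. Genes were ranked by the Ro change in one strain and the RA change was read in the other strain, so that no array was shared. The median RA change of the 300 genes Ro lowered most minus that of the 300 it raised most was 0.37 with Ro ranked in BALB/c (medians 0.25 and -0.13) and 0.138 with Ro ranked in BL6 (medians -0.05 and -0.19). The medians of all genes were 0.06 and -0.02 in these pairings, so the genes Ro lowered lay above all genes in the first pairing and below them in the second, while the genes Ro raised lay below in both. The hypothesis stays open, and the correlation over all genes without shared arrays was -0.0303 and -0.0473.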
